A study of Mus musculus with 24 samples.

How the data were processed

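Total RNA from livers of male C57BL/6J mice was hybridised to 24 2-colour Steroltalk V2 arrays, 6 for each of 4 genotypes: wild type, CAR deficient, PXR deficient and CAR/PXR deficient. Steroltalk is a small spotted array directed at cholesterol and drug metabolism. Per the labels, the Cy5 channel of every array held liver RNA of mice given 40 mg/kg PCN in 5% DMSO in corn oil by intraperitoneal injection and killed after 12 h. The Cy3 channel held a pool of RNA from vehicle-injected mice of the same genotype, and no dye was swapped. PCN is pregnenolone carbonitrile, an activator of rodent PXR. The labels also state that RNA of 6 replicates was pooled, and they describe the pool both as untreated and as vehicle-treated. Whether the 6 arrays of a genotype carried 6 animals was therefore not settled, and p-values here measure the spread between arrays, which may be technical. Groups and replicate numbers came from the sample titles.

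The deposited scanner files give, for each of 1440 spots in 6 blocks, the mean foreground and median local background intensity of both channels, on a linear scale and without normalization per the file headers. They also give the percent of saturated pixels of each spot and a flag score, where -50 marks a spot that was not found, per the file headers. The image analysis software and its settings were not given in the sources used here. The authors' deposited value table holds 1 log2 value per probe and array. Set against the scanner values of the same array, its columns ran in the direction of Cy5 over Cy3, with correlations over probes of 0.41 to 0.99 with the raw log2 ratios and slopes of 0.27 to 0.94. Column medians were -0.37 to 0.17, and 22 to 85 values per column were missing. How the authors scaled and centred these values, and how they treated background, stayed unknown, so the table served as an alternative. All its value columns belonged to the 24 arrays.

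Median foreground per array was 74 to 658 in Cy5 and 122 to 835.5 in Cy3, over median backgrounds of 0 to 249.5 and 36 to 228. Between 10.9% and 31.8% of the spots other than controls were not found. At most 1 spot per array had more than 50% of its pixels saturated in Cy3 and 0 in Cy5. The median SE over probes was 0.07 for responses, 0.10 for differences and 0.14 for the interaction.

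The analysis used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected with normexp and an offset of 50, ratios were normalised within each array by loess over all spots with weight 0 for control spots, and the spots of a probe were averaged. The array held 320 probes, of which 31 were controls and were left out, leaving 284 mouse and 5 human probes. A supplied platform table named 147 of these 289 probes with a single gene each, all 147 matched a gene identifier of the GRCm38.p6 annotation, 0 symbols changed, and 0 probes had several genes. The other 142 probes are unnamed here and appear by their identifier. Genomic positions of the probes are not given here. A probe was tested if at least 50% of its spots were found on at least 6 arrays, which held for 251 probes, 133 of them named and 118 unnamed. Several probes existed for 3 genes. The 2 tested Ppargc1a probes gave like responses (-0.70 and -0.62 in wild type), the Actb probes gave 0.39 and 0.26 in CAR-deficient mice, and the Gapdh probes lay between -0.11 and 0.16 in PXR-deficient mice. In lists and among named genes a gene counted once, by its brightest probe.

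The log2 ratio of PCN over vehicle was fitted by limma with 1 mean per genotype over the 24 arrays, with empirical Bayes moderation. Each mean was tested against 0 (the response). The 5 differences between genotypes were tested, together with the interaction of the 2 gene losses and an F test over the 4 genotypes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the probes of each comparison, with a threshold of 0.05. Each vehicle pool is 1 control sample, so a response leaves out the spread among vehicle animals and holds any dye effect of the probe. Differences between genotypes cancel a dye effect that is constant across arrays, but not differences between the vehicle pools. Values are mean log2 ratios ± SE over 6 arrays unless stated.

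Gene lists were tested with camera at a preset correlation of 0.01, each with at least 5 measured genes: drug oxidation, hepatic transporters, cholesterol biosynthesis, the SREBP pathway with cholesterol transport, bile acid synthesis, nuclear receptors, circadian clock, glucose metabolism and steroid hormone synthesis. These are 9 of 20 lists. For levels in a single channel, arrays were also normalised by Aquantile after loess. Such levels are compared between arrays, so they hold any shift of both channels that normalization left. Pools were compared without a test, at a difference of at least 2-fold and with the probe found on at least 3 arrays of both genotypes, because the 6 arrays of a genotype carry the same pool.

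Genes were named by this rule: Nr1i2 and Nr1i3; per response up to 10 largest rises and 10 largest falls past the threshold; per difference from wild type up to 6 in each direction; for the interaction and for CAR/PXR deficient minus PXR deficient up to 3 in each direction; fixed genes wherever measured, among them Cyp3a11, Cyp2b10, Cyp2c29, Cyp7a1, Cyp8b1, Abcc2, Abcc3, Slco1a4, Ugt1a1, Por, Alas1, Nr1d1, Arntl, Per1, Per2 and Dbp; and the 3 largest wild-type members of each list, or all members of lists of up to 6. Of these, Cyp2b10, Cyp2c29, Ugt1a1, Por, Nr1d1, Arntl and Dbp have no named probe here, and the Per1 probe was not tested. Genes named outside this rule are said to be chosen after their values were seen. The groups, tests, lists, naming rule and most alternative settings were fixed before the data were examined.

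Scan coordinates placed 3 arrays of each genotype at each of 2 positions on the slide. Slide numbers and scan dates were not used here. Luciferase RNA was added as a reference per the labels, but its probes are not named here, so centring on it was not run. Position was chosen as a setting after seeing the data, as was turning the ratios of the CAR/PXR-deficient arrays, and likewise pairs of arrays taken as probable slides and leaving out spots that were not found. Position was added as a block and each position was also fitted alone. The other alternatives were other background corrections, median centring, print-tip loess, scale normalization, the authors' values, other probe filters, array weights, medians over spots, a fold threshold of 1.5, fits on fewer genotypes, leaving out each array, and fry or an estimated correlation for the lists. Of 276 pairs of arrays, 0 were identical, and the highest correlation was 0.97. The limma steps were tested on simulated data over 251 probes. For the wild-type response, 11 of 20 simulated changes of 0.25, 18 of 20 of 0.5 and 20 of 20 of 1 on the log2 scale were found, with 1 false call among 191 unchanged probes. For PXR deficient minus wild type, 5, 16 and 20 of 20 were found, with 0 false calls. The simulated noise was independent between probes and arrays, beside a smooth dye trend. It held no dye effect of single probes, no difference between vehicle pools and no array pattern shared by probes, so the false-call counts do not cover these.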

Results

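The series addressed how PCN changes hepatic genes of drug metabolism, cholesterol homeostasis and circadian rhythm, and which of these changes go with the xenobiotic receptors CAR (Nr1i3) and PXR (Nr1i2). Each of the 24 arrays compared liver RNA of PCN-treated mice with the vehicle pool of the same genotype, 6 arrays per genotype, and 251 probes were tested. Log2 ratios correlated between arrays of a genotype at 0.69 to 0.87 in wild type, 0.38 to 0.88 in CAR deficiency, 0.14 to 0.82 in PXR deficiency and 0.84 to 0.97 in CAR/PXR deficiency, over probes. Between genotypes, the mean profile of wild type correlated with CAR deficient at 0.82, with PXR deficient at 0.16 and with CAR/PXR deficient at -0.15. The mean profile of CAR/PXR deficient correlated with CAR deficient at -0.48 and with PXR deficient at -0.56. Single CAR/PXR-deficient arrays correlated with CAR-deficient arrays at -0.80 to 0.04, with PXR-deficient arrays at -0.77 to 0.03 and with wild-type arrays at -0.37 to 0.07, and wild-type with PXR-deficient arrays at -0.49 to 0.45. In CAR/PXR deficiency ST_Mm_277, ST_Mm_279 and ST_Mm_280 had mean ratios of 5.92, 5.81 and 5.09, where the SD over probes was 0.67 to 0.78 per array. These probes therefore weigh heavily in every correlation with this genotype and within it. Correlations without them were not computed, so the negative values do not show an opposite response over most probes. The labels give the same dye to PCN on all arrays, so the direction was kept. Probes are not independent replicates.

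The receptor transcripts were measured by 1 probe each. In the PCN channel, Nr1i2 had a normalised log2 intensity of 7.69 ± 0.22 (SD, n = 6) in wild type, 7.76 ± 0.29 in CAR deficiency, 7.91 ± 0.25 in PXR deficiency and 8.34 ± 0.30 in CAR/PXR deficiency. The probe for Nr1i2 thus did not differ from wild type in PXR-deficient mice (0.22 ± 0.15 SE, limma adjusted p = 6.5e-01), and was higher in CAR/PXR-deficient mice (0.65 ± 0.15, adjusted p = 3.0e-03), a call that ended without background correction (0.58). Nr1i3 was at 8.01 ± 0.18 (SD, n = 6) in wild type, 7.71 ± 0.08 in CAR deficiency, 8.13 ± 0.40 in PXR deficiency and 7.71 ± 0.12 in CAR/PXR deficiency. Its difference from wild type was -0.31 ± 0.14 SE in CAR deficiency (limma adjusted p = 2.7e-01) and -0.30 ± 0.14 in CAR/PXR deficiency (adjusted p = 1.6e-01). Where these probes lie relative to the deleted part of each gene is not known here, so their levels check nothing about the labels.

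In wild-type mice, PCN raised Cyp3a genes, Mbtps1, Slco1a4 and Alas1. Cyp3a11, a main drug-oxidising cytochrome P450 of mouse liver, rose 7.38-fold (log2 2.88 ± 0.14, limma adjusted p = 3.8e-15), Cyp3a41a rose 6.99-fold (2.80 ± 0.12, adjusted p = 1.5e-16) and Cyp3a13 rose 2.31-fold (1.21 ± 0.07, adjusted p = 3.5e-13), each higher on 6 of 6 arrays. Mbtps1, a protease that activates the SREBP transcription factors, rose 2.14-fold (1.10 ± 0.09, adjusted p = 1.2e-10, 6 of 6). The organic anion uptake transporter Slco1a4 rose 1.67-fold (0.74 ± 0.14, adjusted p = 3.7e-04, 6 of 6), and Alas1, the rate-limiting enzyme of heme synthesis, rose 1.28-fold (0.36 ± 0.09, adjusted p = 3.9e-03, 6 of 6). Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, fell by 0.70 on the log2 scale (SE 0.11, adjusted p = 3.9e-05, 6 of 6). Fgb, the fibrinogen beta chain, fell by 0.67 (SE 0.13, adjusted p = 3.0e-04, 6 of 6), as did the complement regulator C4bp (SE 0.11, adjusted p = 7.1e-05, 6 of 6).

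Further wild-type rises were Apoa1, the main protein of high-density lipoprotein (0.44), Cyp4b1 (0.31) and the unnamed probes ST_Mm_051 (1.72) and ST_Mm_304 (0.44). Further falls were the histone acetyltransferase Crebbp (-0.50), C-reactive protein Crp (-0.41), the growth factor Igf1 (-0.39, 5 of 6 arrays) and the unnamed probes ST_Mm_281 (-0.58), ST_Mm_265 (-0.47), ST_Mm_225 (-0.47) and ST_Mm_015 (-0.39). Crp (-0.36) and Igf1 (-0.32) did not pass with median centring, nor did Apoa1 in the authors' values (0.02). ST_Mm_281 did not pass with median centring (-0.50) or without wild-type array 1 (-0.53), 2 (-0.51), 4 (-0.53) or 5 (-0.52). The export pumps Abcc2 (0.09 ± 0.05) and Abcc3 (0.03 ± 0.05), the bile acid synthesis enzymes Cyp7a1 (0.06 ± 0.07) and Cyp8b1 (-0.02 ± 0.05), Per2 (0.05 ± 0.07) and Nr1i3 (0.06 ± 0.04) did not pass. Nr1i2 passed at 0.22 ± 0.08 (limma adjusted p = 4.8e-02, 6 of 6), a call that ended in 25 of 39 alternatives, 18 of them with a single array left out. Cyp3a11, Cyp3a41a and Cyp3a13 belong to the same gene family, and cross-hybridisation between their probes was not excluded. The values of the Cyp3a probes are therefore uncertain as measures of the single genes and may not be separate results.

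Of 251 probes, 79 passed in wild type: 42 rose and 37 fell, 10 of them by at least 1.5-fold, and 116 had an unadjusted p under 0.05. The count was 78 with position as a block and 45 and 12 at each position alone with 3 arrays per genotype. Without wild-type array 1, and likewise without wild-type array 2, 47 passed. Median centring gave 38 calls, 13 up and 25 down, or 34.2% higher against 53.2%.

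Of 14 measured drug oxidation genes, 5 rose in wild type, the Cyp3a genes with Alas1 and Cyp2a12 (0.21), 1 fell, Cyp2j5 (-0.28), and 8 did not pass (7 up and 3 down adjusted over the list alone). Cyp2a12 and Cyp2j5 were chosen after their values were seen. Of 9 genes of the SREBP pathway, 4 rose, among them Mbtps1, Srebf1 (0.23) and Srebf2 (0.23), and 1 fell (4 and 2 adjusted over the list alone). Of 28 nuclear receptors and partners, 8 rose, among them Nr2c1 (0.28) and Nr5a1 (0.28), and 1 fell, Ppargc1a (10 and 2 adjusted over the list alone). Of 13 transporters, Slco1a4 and the bile acid transporter Slc10a2 (0.27) rose and the cholesterol efflux pump Abca1 fell by 0.29 (2 and 1 adjusted over the list alone). Of 5 bile acid genes, Cyp46a1 rose (0.20) and Cyp27a1 fell (-0.17), with Ch25h at 0.02 (1 and 1 adjusted over the list alone). Of 8 cholesterol biosynthesis genes, Mvd (0.25) rose and Ebp (-0.19) fell, each with a limma adjusted p of 4.9e-02 on 6 and 5 of 6 arrays, and Lss was at 0.20 (2 and 1 adjusted over the list alone). Gckr, the regulator of glucokinase, fell by 0.26 on 5 of 6 arrays as the 1 call among 5 glucose genes, with G6pc at -0.22, Sirt1 at -0.13, Pklr at -0.01 and Foxo1 at 0.00. Cyp11a1 fell by 0.20 as the 1 call among 6 steroid hormone genes, with Cyp11b2 at 0.12, Cyp26a1 at 0.09, Cyp21a1 at 0.03, Cyp17a1 at -0.03 and Cyp24a1 at -0.01. These last counts were the same adjusted over the list alone. Of 5 clock genes 0 passed by limma, nor adjusted over the list alone: Rora 0.12, Nr1d2 0.10, Per2 0.05, Per3 -0.09 and Cry1 -0.09. The Per3 probe was above background on 1 of 6 wild-type and 1 of 6 PXR-deficient arrays, so its response was not measured well there. The probes of Pklr, Sirt1 and Srebf2 were above background on 3, 4 and 4 of 6 wild-type arrays.

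No list passed camera in wild type. Drug oxidation had an adjusted p = 0.283, and adjusted p = 0.739 with an estimated correlation. Over the 4 responses and 3 differences from wild type, 3 of 63 list tests passed camera and 0 of these held with an estimated correlation. The median, mean and test of a list differed in sign in 16 of 63 tests and in 0 of the 3 that passed. With median centring the list passed camera (adjusted p = 0.0307), and it passed fry (adjusted p = 2.8e-07), which tests the list against no change rather than against the other genes. Without wild-type array 1, the calls of Cyp27a1 (-0.13), Cyp46a1 (0.16), Nr2c1 (0.24), Nr5a1 (0.22), Srebf1 (0.20) and Srebf2 (0.18) ended. Without wild-type array 2, those of Cyp46a1 (0.18), Nr2c1 (0.25), Nr5a1 (0.19), Srebf1 (0.18) and Srebf2 (0.20) ended, and without wild-type array 5 those of Nr5a1 (0.26) and Srebf1 (0.20). The Mvd call ended in 17 and the Ebp call in 19 of the 24 fits with a single array left out, and over all alternatives their values were 0.18 to 0.33 and -0.24 to -0.07. Cyp27a1 also ended with print-tip loess and with medians over spots (-0.12 each), and Nr5a1 with the wild-type arrays alone (0.28). With median centring or the authors' values, the calls of Abca1 (-0.23 and -0.22), Srebf1 (0.22 and 0.31), Srebf2 (0.17 and 0.30), Cyp27a1 (-0.09 and -0.08), Cyp11a1 (-0.14 and -0.07) and Nr5a1 (0.34 and 0.21) ended in both, Slc10a2 (0.18) and Cyp46a1 (0.27) in the former, and Gckr (-0.15) and Nr2c1 (0.35) in the latter.

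In CAR-deficient mice, PCN still raised the drug-oxidising Cyp3a genes. Cyp3a11 rose 4.62-fold (2.21 ± 0.14, limma adjusted p = 1.8e-12), Cyp3a41a rose 3.81-fold (1.93 ± 0.12, adjusted p = 9.0e-13) and Cyp3a13 rose 1.72-fold (0.79 ± 0.07, adjusted p = 4.5e-09), each on 6 of 6 arrays. Mbtps1 rose 1.47-fold (0.56 ± 0.09, adjusted p = 3.1e-05, 6 of 6), and Alas1 rose 1.34-fold (0.42 ± 0.09, adjusted p = 1.2e-03, 6 of 6). Ppargc1a fell by 0.65 (SE 0.11, adjusted p = 8.7e-05, 6 of 6). Slco1a4 did not pass (0.32 ± 0.14, adjusted p = 1.5e-01, 5 of 6). The largest falls were those of the unnamed probes ST_Mm_280 (-1.72, SD 1.27, 6 of 6), ST_Mm_277 (-1.36, SD 1.59, 5 of 6) and ST_Mm_279 (-1.29, SD 1.54, 5 of 6).

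Actb (0.39), ST_Mm_051 (1.46), ST_Mm_304 (0.71), ST_Mm_037 (0.34) and ST_Mm_222 (0.32) also rose in CAR deficiency. The bile salt export pump Abcb11 (-0.45), Fgb (-0.40), the drug efflux pump Abcb1a (-0.38), ST_Mm_270 (-0.49), ST_Mm_015 (-0.46) and ST_Mm_209 (-0.38) fell. Abcb11 did not pass without CAR-deficient array 2 (-0.35), Fgb not without arrays 2 (-0.26) or 3 (-0.39), among 8 of 40 alternatives that ended it, and Abcb1a not without arrays 1 (-0.38), 2 (-0.32) or 5 (-0.37). With median centring, Abcb11 (-0.34), Fgb (-0.29), Abcb1a (-0.27) and ST_Mm_270 (-0.40) did not pass. With scale normalization Fgb (-0.37), ST_Mm_277 (-1.30) and ST_Mm_279 (-1.22) did not pass, and with the genotype's arrays alone Fgb, ST_Mm_277, ST_Mm_279, ST_Mm_270 and ST_Mm_209 did not. The calls of ST_Mm_222 and ST_Mm_270 ended in 12 and 8 of 40 alternatives, with values of 0.23 to 0.40 and -0.59 to -0.35, and ST_Mm_209 ended in the authors' values (-0.35). Without CAR-deficient array 2 ST_Mm_277 was -0.78 and ST_Mm_279 -0.73, and without array 1 ST_Mm_209 was -0.21, all still past the threshold. Slco1a4 passed with array weights (0.50), scale normalization (0.44) and without CAR-deficient array 1 (0.52), and Cyp7a1 without background correction (-0.29), with median centring (-0.25) and without array 1 (-0.25). Abcc2 (0.08), Abcc3 (0.13), Cyp7a1 (-0.16), Cyp8b1 (-0.14), Per2 (-0.14), Nr1i2 (0.13) and Nr1i3 (0.07) did not pass. In all, 40 probes passed, 15 up and 25 down, 10 by at least 1.5-fold, with 39 under the position block and 28 and 8 at each position alone. With the genotype's arrays fitted alone, 23 passed.

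As a group, 5 of 14 drug oxidation genes rose in CAR deficiency, the Cyp3a genes, Alas1 and Cyp1a2 (0.29, chosen after its value was seen), and 9 did not pass (5 adjusted over the list alone). This list passed camera upward (adjusted p = 0.00268), with adjusted p = 0.271 with an estimated correlation. Of 13 transporters, 3 fell, Abcb11, Abcb1a and Abcb1b (-0.31), and 10 did not pass (1 up and 3 down adjusted over the list alone). Of 8 cholesterol biosynthesis genes, Ebp (-0.36) and Fdft1 (-0.27) fell, and of 5 bile acid genes Ch25h (-0.19) fell (2 and 2 adjusted over the list alone). Mbtps1 was the 1 rise among 9 SREBP pathway genes (2 adjusted over the list alone) and Ppargc1a the 1 fall among 28 nuclear receptors and partners (1 adjusted over the list alone). Among 5 clock, 5 glucose and 6 steroid hormone genes limma called 0, and 0 adjusted over each list alone. Abcb1b, Fdft1 and the values of Ebp and Ch25h in this genotype were chosen after they were seen.

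In PXR-deficient mice the response of Cyp3a11 was 0.30 ± 0.14 (limma adjusted p = 1.0e-01, higher on 5 of 6 arrays) and did not pass, nor did Slco1a4 (-0.04 ± 0.14) or Alas1 (0.14 ± 0.09). Cyp3a11 passed with print-tip loess (0.35), array weights (0.40) and the authors' values (0.48). Slco1b2, a hepatic uptake transporter of organic anions, rose 1.68-fold (0.75 ± 0.08, adjusted p = 1.6e-07, 6 of 6), and G6pc, the last enzyme of gluconeogenesis, rose 1.55-fold (0.63 ± 0.15, adjusted p = 1.9e-03, 6 of 6). The canalicular export pump Abcc2 rose 1.31-fold (0.39 ± 0.05, adjusted p = 5.0e-06, 6 of 6). Abca1, which exports cholesterol, fell by 0.94 (SE 0.07, adjusted p = 5.5e-10, 6 of 6), Fgb fell by 0.87 (SE 0.13, adjusted p = 1.2e-05, 5 of 6), Abcb11 fell by 0.67 (SE 0.12, adjusted p = 1.9e-04, 6 of 6) and Abcb1a fell by 0.58 (SE 0.11, adjusted p = 3.9e-04, 6 of 6). Ebp, an isomerase of cholesterol biosynthesis, fell by 0.47 (SE 0.07, adjusted p = 2.6e-05, 6 of 6). Without PXR-deficient array 2 the Abcb1a value was -0.37 and still passed. Abcb11 (-1.51), Abcb1a (-1.61) and Ebp (-0.93) were all lowest on that array, so their falls may not be separate results.

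The drug oxidation genes Cyp2a12 (0.45) and Cyp2f2 (0.45) and the probes ST_Mm_137 (0.63), ST_Mm_295 (0.50), ST_Mm_051 (0.49), ST_Mm_222 (0.46), ST_Mm_220 (0.44) and ST_Mm_314 (0.43) rose in PXR deficiency, and ST_Mm_280 (-1.16), ST_Mm_292 (-0.89), ST_Mm_279 (-0.88), ST_Mm_291 (-0.62) and ST_Mm_281 (-0.49) fell. Cyp8b1 (0.18) and Nr1i3 (0.20) rose and Cyp7a1 fell by 0.20, while Abcc3 (0.11), Per2 (-0.05) and Nr1i2 (0.08) did not pass. The calls of ST_Mm_279 and ST_Mm_281 ended in 9 and 19 of 40 alternatives, with values of -1.03 to -0.57 and -0.75 to -0.31. With median centring ST_Mm_292 (-0.58) and ST_Mm_291 (-0.38) did not pass, nor ST_Mm_291 in the authors' values (-0.39). Cyp7a1 did not pass without PXR-deficient array 2 (-0.13) or 3 (-0.21) or in the authors' values (-0.23), Nr1i3 not with median centring (0.14), and Cyp8b1 with neither median centring (0.20) nor the authors' values (0.13). In all, 88 probes passed, 45 up and 43 down, 10 by at least 1.5-fold. The position block gave 84, each position alone 27 and 31, and the genotype's arrays alone 54. The share of higher calls was 51.1%, against 68.2% of 44 calls with median centring (30 up, 14 down) and 65.6% with the authors' values (40 up, 21 down).

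By list, 4 of 14 drug oxidation genes rose in PXR deficiency, Cyp2a12, Cyp2f2, Cyp2d22 (0.33) and Cyp2j5 (0.33), and Cyp2b13 (-0.20) fell (4 and 2 adjusted over the list alone). The list passed camera upward (adjusted p = 0.0474), with adjusted p = 0.668 with an estimated correlation. Of 13 transporters, Slco1b2 and Abcc2 rose and Abca1, Abcb11 and Abcb1a fell (2 and 3 adjusted over the list alone). All 5 bile acid genes passed: Cyp8b1 and Cyp27a1 (0.18) rose and Cyp7a1, Cyp46a1 (-0.17) and Ch25h (-0.16) fell (2 and 3 adjusted over the list alone). Of 8 cholesterol biosynthesis genes, Fdft1 (0.27) rose and Ebp, Lss (-0.23) and Mvk (-0.19) fell (1 and 4 adjusted over the list alone). Of 28 nuclear receptors and partners, 2 rose, among them Nr1i3, and 6 fell, Thrb (-0.27), Nr5a1 (-0.25), Nr5a2 (-0.24), Nr2c1 (-0.22), Rxrb (-0.20) and Thra (-0.19) (2 and 5 adjusted over the list alone). Of 9 SREBP pathway genes, 2 rose, among them Insig1 (0.43), which retains SREBP in the endoplasmic reticulum, and 2 fell, among them Scap (-0.12) (2 and 2 adjusted over the list alone). G6pc was the 1 call among 5 glucose genes and Cyp17a1 (-0.30) the 1 among 6 steroid hormone genes (1 each adjusted over the list alone), and limma called 0 of 5 clock genes, with 0 adjusted over the list alone. Cyp2d22, Cyp2j5, Cyp2b13, Fdft1, Mvk, Thra, Thrb, Rxrb, Nr5a2, Scap and Insig1 were chosen after their values were seen. Many of these falls rested on PXR-deficient array 2. Without it Cyp7a1 (-0.13), Cyp46a1 (-0.09), Ch25h (-0.09), Lss (-0.10), Mvk (-0.12), Cyp2b13 (-0.13), Scap (-0.07), Nr2c1 (-0.09), Nr5a1 (-0.10), Nr5a2 (-0.10), Thra (-0.10) and Thrb (-0.13) did not pass, so of the 6 nuclear receptor falls only Rxrb (-0.12) stayed.

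In CAR/PXR-deficient mice the rises were led by unnamed probes and by Fgb. ST_Mm_277 rose 60.4-fold (5.92 ± 0.32, limma adjusted p = 8.6e-14), ST_Mm_279 rose 56-fold (5.81 ± 0.31, adjusted p = 8.6e-14) and ST_Mm_280 rose 34-fold (5.09 ± 0.29, adjusted p = 1.5e-13), each on 6 of 6 arrays. With scale normalization these were larger (7.31, 7.16 and 6.29), and over all alternatives the lowest values were 5.81, 5.71 and 5.01. ST_Mm_277 and ST_Mm_279 followed each other closely over the arrays of all genotypes, so their values may not be separate results. Fgb rose 3.05-fold (1.61 ± 0.13, adjusted p = 8.9e-11, 6 of 6), and Crp, also an acute-phase protein, rose by 0.48 (SE 0.09, adjusted p = 1.6e-04). Slco1b2 fell by 0.90 (SE 0.08, adjusted p = 9.5e-10, 6 of 6), the cytochrome P450 Cyp2c40 by 0.54 (SE 0.08, adjusted p = 1.4e-05, 6 of 6), and the export pumps Abcc3 and Abcc2 fell by 0.38 (SE 0.05, adjusted p = 1.1e-06, 6 of 6) and 0.33 (SE 0.05, adjusted p = 2.2e-05, 6 of 6). Ppp1r3c, a subunit that directs protein phosphatase to glycogen, fell by 0.41 (SE 0.09, adjusted p = 1.7e-03, 6 of 6).

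The probes ST_Mm_292 (2.32), ST_Mm_291 (2.19), ST_Mm_281 (1.87), ST_Mm_284 (0.88), ST_Mm_285 (0.63) and ST_Mm_283 (0.63) also rose in CAR/PXR deficiency, and ST_Mm_139 (-0.46), ST_Mm_217 (-0.45), ST_Mm_211 (-0.40) and ST_Mm_295 (-0.34) fell. Cyp3a11 fell by 0.39 (SE 0.14, limma adjusted p = 4.6e-02, 6 of 6), a call that ended in 19 of 40 alternatives, 10 of them with a single array left out. Its values there were -0.58 to -0.17. ST_Mm_295 did not pass with median centring (-0.23), and Slco1a4 passed with background subtraction (0.96). The Slco1a4 probe was above background on 3 of 6 arrays of this genotype, so its response was not measured well there. Ppargc1a fell by 0.39 and did not pass without CAR/PXR-deficient array 5 (-0.34) or with median centring (-0.25). Cyp8b1 (0.14, 6 of 6) passed at a limma adjusted p of 4.8e-02 and ended in 30 of 40 alternatives, with a value of 0.08 without CAR/PXR-deficient array 6. Alas1 (-0.17), Slco1a4 (0.20), Cyp7a1 (-0.12), Per2 (-0.08), Nr1i2 (0.17) and Nr1i3 (0.04) did not pass. In all, 59 probes passed, 26 up and 33 down, 11 by at least 1.5-fold, with 56 under the position block and 36 and 22 at each position alone. Without CAR/PXR-deficient array 6, 38 passed. The directions in this genotype rest on the dyes given in the labels, and an exchange of RNA before labelling, which was not tested, would turn every ratio here. Then 33 would rise and 26 fall, with Fgb at -1.61, ST_Mm_277 at -5.92, ST_Mm_279 at -5.81, ST_Mm_280 at -5.09, Slco1b2 at 0.90 and Cyp3a11 at 0.39.

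Of 14 drug oxidation genes, 6 fell in CAR/PXR deficiency, Cyp3a11, Cyp2c40, Cyp2e1 (-0.32), Cyp2a12 (-0.30), Cyp2f2 (-0.30) and Cyp2d22 (-0.21), and Cyp3a13 (0.25) rose (1 up and 6 down adjusted over the list alone). Camera did not call the list (adjusted p = 0.0662, and adjusted p = 0.462 with an estimated correlation). Of 13 transporters, Abcc1 (0.36) rose and Slco1b2, Abcc3, Abcc2 and Abcg8 (-0.17) fell (1 and 4 adjusted over the list alone). Of 28 nuclear receptors and partners, 3 rose, among them the bile acid receptor Nr1h4 (0.22), and Ppargc1a fell (2 and 1 adjusted over the list alone). Of 5 glucose genes, Foxo1 (0.19) rose and Gckr (-0.18) fell (1 and 1 adjusted over the list alone). Cyp8b1 was the 1 rise of 5 bile acid genes and Fdps (0.22) of 8 cholesterol biosynthesis genes (0 each adjusted over the list alone). Among 9 SREBP pathway, 5 clock and 6 steroid hormone genes limma called 0, and 0 adjusted over each list alone, and the Per3 probe was not above background on any array of this genotype. Cyp2e1, Cyp2d22, Cyp3a13, Abcc1, Abcg8, Nr1h4, Foxo1 and Fdps were chosen after their values here were seen.

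**Figure D1:**
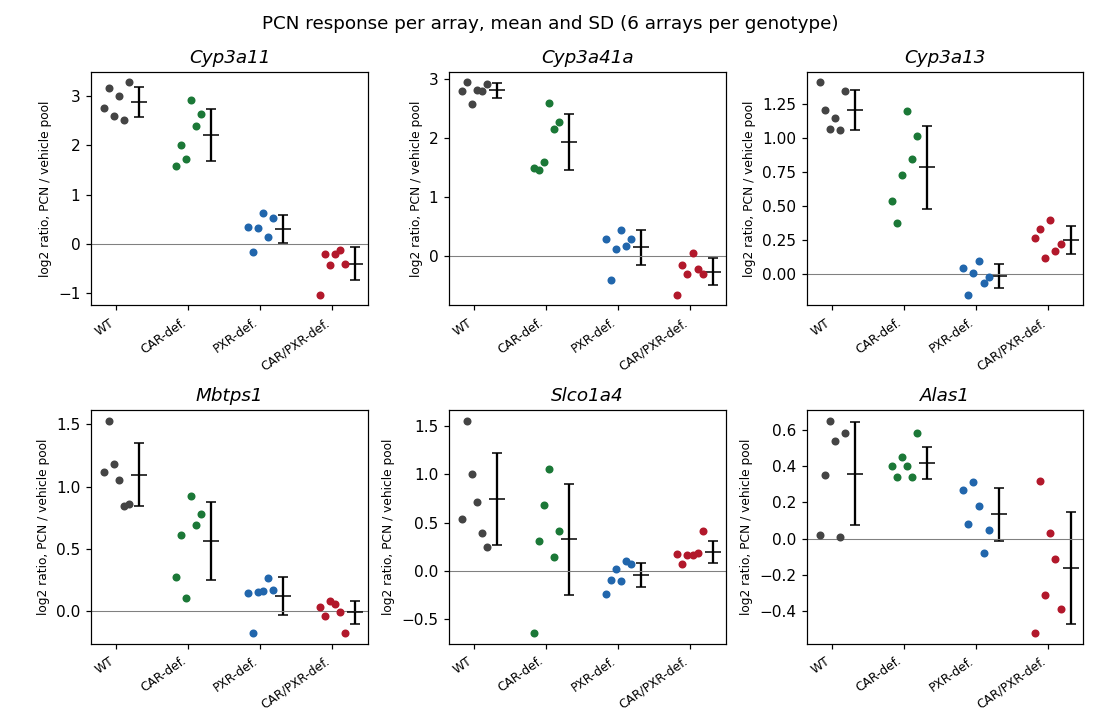
Log2 ratio of PCN over the vehicle pool (vertical axis) for Cyp3a11, Cyp3a41a, Cyp3a13, Mbtps1, Slco1a4 and Alas1 in the 4 genotypes. Points are single arrays (6 per genotype), bars are the mean and SD, and the line marks 0; Cyp3a11 has a mean of 2.88 in wild type, 2.21 in CAR deficiency, 0.30 in PXR deficiency and -0.39 in CAR/PXR deficiency.

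**Figure D2:**
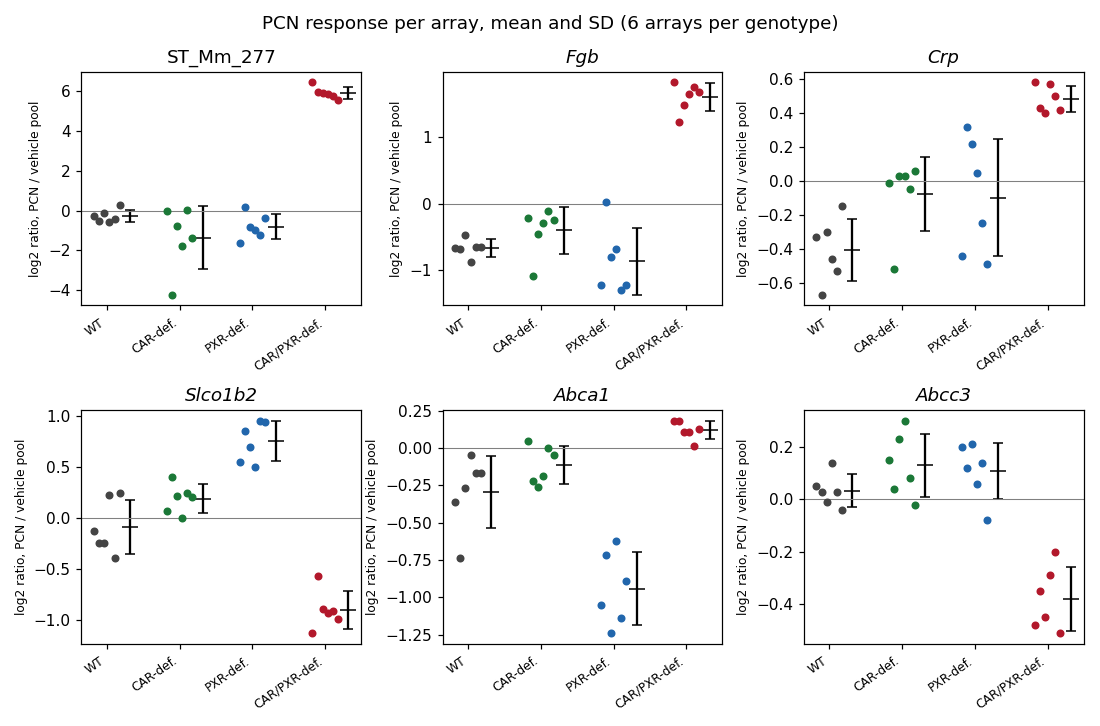
Log2 ratio of PCN over the vehicle pool (vertical axis) for ST_Mm_277, Fgb, Crp, Slco1b2, Abca1 and Abcc3, with single arrays as points, mean and SD as bars and a line at 0. Fgb has a mean of -0.67 in wild type and 1.61 in CAR/PXR deficiency, and Slco1b2 of 0.75 in PXR deficiency and -0.90 in CAR/PXR deficiency.

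CAR-deficient arrays had smaller PCN responses of a few genes, mostly on arrays 1 to 3. Cyp3a41a responded less by -0.87 ± 0.17 in CAR-deficient than in wild-type mice (limma adjusted p = 4.8e-03), Mbtps1 by -0.54 ± 0.12 (adjusted p = 2.3e-02) and Cyp3a13 by -0.42 ± 0.10 (adjusted p = 3.0e-02). For each, 5 of 6 CAR-deficient arrays lay below all wild-type arrays. Over CAR-deficient arrays 1 to 6 in order, Cyp3a41a was at 1.5, 1.46, 1.59, 2.6, 2.16 and 2.28. Mbtps1 was at 0.27, 0.61, 0.1, 0.92, 0.69 and 0.78, and Cyp3a13 at 0.54, 0.38, 0.73, 1.2, 0.85 and 1.02. The differences thus lay mostly on arrays 1 to 3. These 3 of 251 probes passed and Cyp3a11 did not, with 0 up and 3 down and 39 at an unadjusted p under 0.05. The Cyp3a41a difference did not pass with median centring (-0.75), scale normalization (-0.59) or the authors' values (-0.53), and the Mbtps1 and Cyp3a13 calls ended in 13 and 14 of 40 alternatives, over which their values were -0.71 to -0.35 and -0.51 to -0.27. The count was 4 with position as a block and 0 at each position alone, and 0 with median centring, scale normalization or the authors' values. It was 1 without wild-type array 1 or 2 or CAR-deficient array 1 or 3, 6 without wild-type array 3 and 5 without PXR-deficient array 2. By list, 2 of 14 drug oxidation genes fell (3 adjusted over the list alone) and 1 of 9 SREBP pathway genes (1 adjusted over the list alone), and limma called 0 in each of the other 7 lists. Adjusted over the list alone, 1 bile acid gene was higher and 1 lower, and 1 glucose gene was higher. No list passed camera. In the probes called in both genotypes the responses overlapped: 10 probes rose in both, where independent lists of these sizes share 2.51, and 9 fell in both, against 3.69. A dye effect of the probe that is the same on all arrays would also give shared calls, so this overlap does not by itself show a shared response to PCN.

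Loss of PXR went with smaller responses of Cyp3a genes, Mbtps1 and Slco1a4. The response was lower than in wild type by -2.65 ± 0.17 for Cyp3a41a (limma adjusted p = 3.6e-12), -2.58 ± 0.20 for Cyp3a11 (adjusted p = 1.9e-10), -1.22 ± 0.10 for Cyp3a13 (adjusted p = 6.0e-10), -0.98 ± 0.12 for Mbtps1 (adjusted p = 1.1e-06) and -0.78 ± 0.20 for Slco1a4 (adjusted p = 3.7e-03). It was higher for G6pc (0.84 ± 0.21, adjusted p = 2.8e-03), Slco1b2 (0.84 ± 0.11, adjusted p = 3.1e-06) and Ppp1r3c (0.67 ± 0.13, adjusted p = 4.6e-04). For each of these genes, 6 of 6 PXR-deficient arrays lay beyond all wild-type arrays. The probe ST_Mm_051 was lower (-1.23), and ST_Mm_286 (0.74), ST_Mm_285 (0.71) and ST_Mm_287 (0.66) were higher. Of 251 probes, 117 passed, 57 up and 60 down, 18 by at least 1.5-fold, with 114 under the position block, 43 and 20 at each position alone and 62 with median centring. For 86 of the 117, the normalised levels of the vehicle pools differed by more than those of the PCN-treated samples. This split also depends on any shift of both channels between arrays. For Cyp3a13, the normalised log2 level was 11.43 against 11.74 in wild type in the PCN channel and 11.44 against 10.53 in the vehicle pool. Among probes called in both responses, 6 rose and 7 fell in both, where independent lists share 7.53 and 6.34, 9 that rose in wild type fell in PXR deficiency, and 8 did the reverse.

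By list, 5 of 14 drug oxidation genes had a lower response in PXR deficiency than in wild type, the Cyp3a genes, Cyp1a1 (-0.37) and Cyp2b13 (-0.20), and 4 a higher one, Cyp2j5 (0.61), Cyp2f2 (0.52), Cyp2d22 (0.50) and Cyp2c40 (0.33) (5 and 5 adjusted over the list alone). Of 8 cholesterol biosynthesis genes, 5 were lower, Mvd (-0.49), Lss (-0.43), Fdps (-0.29), Ebp (-0.28) and Mvk (-0.24), and Fdft1 (0.42) was higher (2 up and 5 down adjusted over the list alone). Of 9 SREBP pathway genes, 5 were lower, among them Mbtps1, Srebf1 (-0.36) and Srebf2 (-0.31), and Insig1 (0.65) was higher (2 and 5 adjusted over the list alone). Of 28 nuclear receptors and partners, 12 were lower and Ppargc1a (0.45) was higher (1 and 13 adjusted over the list alone). Transporters had 2 of 13 higher, Slco1b2 and Abcc2 (0.30), and 3 lower, Slco1a4, Abca1 (-0.65) and Slc10a2 (-0.30) (2 and 3 adjusted over the list alone). Bile acid genes had 2 of 5 higher and 2 lower (2 and 3 adjusted over the list alone), glucose genes 2 of 5 higher, G6pc and Gckr (0.36) (2 adjusted over the list alone), and steroid hormone genes 1 of 6 higher and 2 lower (1 and 2 adjusted over the list alone). Of 5 clock genes limma called 0, and 0 adjusted over the list alone. No list passed camera. Cyp1a1, Cyp2b13, Cyp2j5, Cyp2f2, Cyp2d22, Cyp2c40, Fdft1, Fdps, Mvk and Insig1 were chosen after their values were seen. Without PXR-deficient array 2 Fdps (-0.18) and Cyp2b13 (-0.13) did not pass, nor Cyp2c40 without PXR-deficient array 4 (0.22). Mvd, Lss, Srebf1, Nr2c1, Nr5a1 and Cyp46a1 shared a pattern over the arrays of both genotypes, so their lower responses may not be separate results.

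Loss of both receptors went with smaller responses of the Cyp3a genes and, as labelled, a rise of Fgb in place of its wild-type fall. Cyp3a11 was lower by -3.28 ± 0.20 (limma adjusted p = 6.0e-13), Cyp3a41a by -3.06 ± 0.17 (adjusted p = 6.4e-14), Mbtps1 by -1.11 ± 0.12 (adjusted p = 4.8e-08), Cyp3a13 by -0.96 ± 0.10 (adjusted p = 3.4e-08) and Slco1b2 by -0.81 ± 0.11 (adjusted p = 2.8e-06). Fgb was higher by 2.28 ± 0.18 (adjusted p = 7.5e-11) and Crp by 0.89 ± 0.13 (adjusted p = 3.1e-06). The unnamed probes ST_Mm_277 (6.19 ± 0.46), ST_Mm_279 (6.10 ± 0.44), ST_Mm_280 (5.82 ± 0.41), ST_Mm_292 (2.46) and ST_Mm_281 (2.45) were higher and ST_Mm_051 (-1.95) was lower. For each of these, 6 of 6 CAR/PXR-deficient arrays lay beyond all wild-type arrays. In all, 47 probes passed, 25 up and 22 down, 19 by at least 1.5-fold, with 46 under the position block, 28 and 24 at each position alone and 31 with median centring. For 32 of the 47, the vehicle pools differed by more than the PCN-treated samples (59 of 109 with the CAR/PXR-deficient channels turned). For Cyp3a13, the normalised log2 level was 11.61 against 11.74 in wild type in the PCN channel and 11.36 against 10.53 in the vehicle pool. For Cyp3a11 these were 12.71 against 13.98 and 13.10 against 11.09, and for Cyp3a41a 12.69 against 14.11 and 12.95 against 11.31. The larger part thus lay between the pool levels for Cyp3a13, and both sides differed for Cyp3a11 and Cyp3a41a. Any shift of both channels between arrays would change this split. With the CAR/PXR-deficient ratios turned, Cyp3a11 (-2.49), Cyp3a41a (-2.55), Cyp3a13 (-1.46) and Mbtps1 (-1.08) would still be lower, Fgb (-0.94), ST_Mm_277 (-5.64), ST_Mm_279 (-5.52) and ST_Mm_280 (-4.36) lower rather than higher, Slco1b2 higher and Crp not different (-0.07), with 53 probes up and 56 down. Of 14 drug oxidation genes, 7 were lower, among them Alas1 (-0.52) and Cyp2a12 (-0.51), and 0 higher (1 up and 8 down adjusted over the list alone). The list passed camera downward (adjusted p = 0.000682), with adjusted p = 0.165 with an estimated correlation. With the ratios turned it would not pass (adjusted p = 0.964), with 4 genes higher and 4 lower, and Alas1 (-0.19) and Cyp2a12 (0.08) would not pass. Of 13 transporters, Abcc1 (0.56) and Abca1 (0.41) were higher and Slco1b2, Abcc2 (-0.42) and Abcc3 (-0.41) lower (2 and 4 adjusted over the list alone). Mbtps1 and Srebf2 (-0.31) were lower among 9 SREBP pathway genes (2 adjusted over the list alone), and Cry1, a clock repressor, was higher by 0.23 as the 1 call of 5 clock genes (1 adjusted over the list alone). In the other 5 lists limma called 0, and 0 adjusted over each list alone. With the ratios turned, 6 transporters would be higher and 2 lower, 1 SREBP pathway gene higher and 3 lower, 2 nuclear receptors and partners higher and 12 lower, and Abca1 (0.18) and Cry1 (-0.05) would not pass. Likewise 1 cholesterol biosynthesis gene would be higher and 3 lower, 1 bile acid gene higher and 1 lower, and 1 glucose and 1 steroid hormone gene higher. Abcc1 was chosen after its value was seen.

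Against PXR deficiency alone, the added loss of CAR went with a lower response of Slco1b2 (-1.65 ± 0.11, limma adjusted p = 5.2e-12, 6 of 6 arrays beyond all PXR-deficient arrays). The response of ST_Mm_277 (6.73 ± 0.46), ST_Mm_279 (6.68 ± 0.44) and ST_Mm_280 (6.25 ± 0.41) was higher, and that of ST_Mm_137 (-0.96) and ST_Mm_295 (-0.85) lower. Fgb was higher by 2.48 ± 0.18 (adjusted p = 1.2e-11, 6 of 6), and Abcc2 lower by -0.72 ± 0.07 (adjusted p = 1.4e-08, 6 of 6). The count was 95, 53 up and 42 down, 27 by at least 1.5-fold, with 98 under the position block, 37 and 37 at each position alone and 43 with median centring. For 66 of the 95, the vehicle pools differed by more than the PCN-treated samples (27 of 52 with the CAR/PXR-deficient channels turned). The share of higher calls was 55.8%, against 37.2% with median centring (16 up, 27 down) and 38.2% with the authors' values (26 up, 42 down). Of probes called in both responses, 4 rose in both and 2 fell in both, where independent lists share 4.66 and 5.65, 15 rose in PXR deficiency and fell in CAR/PXR deficiency, and 6 did the reverse. With the CAR/PXR-deficient ratios turned, 15 would rise in both and 6 fall in both, 52 differences would pass (22 up, 30 down), Fgb (-0.74), ST_Mm_277 (-5.10), ST_Mm_279 (-4.93) and ST_Mm_280 (-3.92) would be lower, and Slco1b2 (0.16) and Abcc2 (-0.06) would not pass. Such a gain in agreement was not seen for the other genotypes. In wild type and CAR/PXR deficiency 1 probe rose and 10 fell in both as labelled, against 4.35 and 4.86 for independent lists. Turned, 5 would rise and 6 fall in both, with 1 and 10 opposite. In CAR and CAR/PXR deficiency 1 rose and 6 fell in both, against 1.55 and 3.29. Turned, 3 would rise and 4 fall in both, with 1 and 6 opposite.

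Against CAR deficiency alone, the response in CAR/PXR deficiency was lower for Cyp3a11 (-2.60 ± 0.20, limma adjusted p = 5.3e-11, 6 of 6 arrays beyond all CAR-deficient arrays) and higher for Fgb (2.01 ± 0.18, adjusted p = 8.9e-10, 6 of 6). Here 49 probes passed, 24 up and 25 down, 14 by at least 1.5-fold, with 47 under the position block, 27 and 24 at each position alone and 29 with median centring. For 29 of the 49, the vehicle pools differed by more than the PCN-treated samples (37 of 67 with the CAR/PXR-deficient channels turned). With the CAR/PXR-deficient ratios turned, 67 would pass (35 up, 32 down), with Cyp3a11 at -1.81 and Fgb at -1.21.

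The interaction asks whether CAR loss changes the response differently with and without PXR. It was negative for Slco1b2 (-1.93 ± 0.16, limma adjusted p = 4.6e-10), G6pc (-1.12 ± 0.29, adjusted p = 5.5e-03) and ST_Mm_137 (-0.97 ± 0.14), and positive for ST_Mm_277 (7.81 ± 0.65), ST_Mm_279 (7.68 ± 0.62) and ST_Mm_280 (7.23 ± 0.58). It passed for 95 probes, 52 up and 43 down, 36 by at least 1.5-fold, with 92 under the position block, 25 at each position alone, 28 with median centring and 58 with the authors' values. The share of positive values was 54.7%, against 35.7% with median centring (10 up, 18 down). The response differed among the 4 genotypes at 134 probes, with 135 under the position block, 55 and 35 at each position alone, 61 with median centring and 82 with the authors' values. Over all 4 responses, 0 probes rose and 1 fell in every genotype. With the CAR/PXR-deficient ratios turned, 2 would rise and 1 fall in every genotype, 146 probes would differ among genotypes and the interaction would pass for 35 (14 up, 21 down), with ST_Mm_277 at -4.02, ST_Mm_279 at -3.94 and ST_Mm_280 at -2.94 and without Slco1b2 (-0.12) and G6pc (-0.76).

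Normalised vehicle pool levels differed between genotypes at some probes. Each level was compared between arrays, so a shift of both channels on the arrays of a genotype would enter it. Compared with the wild-type pool, Cyp3a11 lay 4.02-fold higher in the CAR/PXR-deficient pool, at a normalised log2 Cy3 intensity of 13.10 ± 0.33 against 11.09 ± 0.33 (SD over 6 arrays of the same pool, a technical spread). Cyp3a41a (1.64) and Cyp2e1 (1.22), an ethanol-oxidising P450, were also higher there on the log2 scale, as were the human probe ST_Hs_332 (2.31) and ST_Mm_211 (1.03). The PCN channel of the same arrays also lay above the wild-type pool: ST_Hs_332 by 2.15, Cyp3a11 by 1.61, Cyp3a41a by 1.38, Cyp2e1 by 0.9 and ST_Mm_211 by 0.62. These higher levels were thus not particular to the pool channel. Lower in the CAR/PXR-deficient pool were ST_Mm_277 (8.82 ± 0.34 against 12.81 ± 0.62), ST_Mm_280 (-3.96), ST_Mm_279 (-3.84), ST_Mm_292 (-1.59) and ST_Mm_281 (-1.30). These were 10 of 228 probes compared. With the CAR/PXR-deficient channels turned, the pool of that genotype would have 8 of these 228 probes at least 2-fold higher and 0 lower, with Cyp3a11 at 12.71, Cyp3a41a at 12.69, ST_Mm_277 at 14.73 and ST_Mm_280 at 12.74, so the lower probes rest on the labels. In the PXR-deficient pool 3 of 237 probes differed by at least 2-fold, Cyp3a41a (1.10), the sterol biosynthesis enzyme Msmo1 (-1.34) and ST_Mm_286 (-1.01), and 1 with median centring. In the CAR-deficient pool 0 of 241 did. With 1 pool per genotype these differences have no replicate check.

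**Figure D3:**
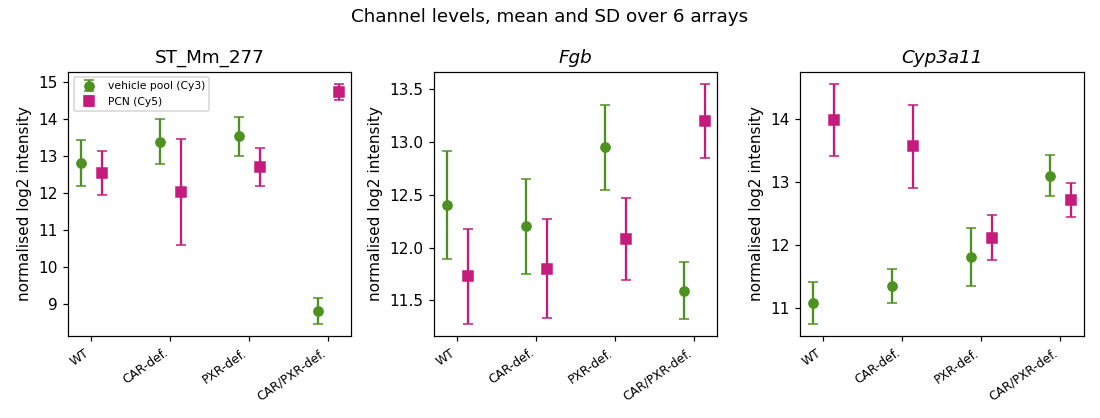
Normalised log2 intensity (vertical axis) of ST_Mm_277, Fgb and Cyp3a11 in the vehicle pool (Cy3, circles) and the PCN-treated samples (Cy5, squares) of the 4 genotypes, as mean and SD over 6 arrays. Cyp3a11 has a vehicle level of 13.10 in CAR/PXR deficiency and 11.09 in wild type, and ST_Mm_277 one of 8.82 and 12.81.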

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

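The tests of vehicle pool levels, PCN-treated levels, exchanged channels, pool side and dye effect were chosen only after the result was seen. The comparisons with other splits of the arrays were fixed before.

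Single arrays lay apart from the other 5 of their genotype in 18 of 140 groups tested, where 7 are expected by chance at 5%. The gap over the range was 0.627 for Cyp3a41a in wild type (array 3), 0.644 for Fgb (array 2) and 0.728 for ST_Mm_209 (array 1) in CAR deficiency, and 0.711 for Abcb1a and 0.764 for Ebp in PXR deficiency (both array 2). In CAR/PXR deficiency it was 0.694 for ST_Mm_279, 0.64 for ST_Mm_292 and 0.662 for Cyp3a11, all on array 1. Of the bile acid and clock genes, it was 0.629 for Cyp7a1 and 0.633 for Per2 in CAR deficiency (both array 1), 0.856 for Cyp7a1 in PXR deficiency (array 2), 0.757 for Cyp8b1 in CAR/PXR deficiency (array 6), 0.654 for Per3 (array 6) and 0.628 for Cry1 (array 5) in wild type. It was 0.894 for Nr1i2 and 0.644 for Slco1a4 (both array 6) and 0.69 for Nr1i3 (array 5) in CAR/PXR deficiency, and 0.644 for Pklr in wild type (array 3).

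The response differed between genotypes at 3 probes for CAR deficient minus wild type, where the highest count among the other 99 of 100 splits of the arrays was 2, at 117 for PXR deficient minus wild type (highest other 80) and at 47 for CAR/PXR deficient minus wild type (highest other 25). It differed at 95 probes for CAR/PXR deficient minus PXR deficient (highest other 45) and at 49 for CAR/PXR deficient minus CAR deficient (highest other 18). The interaction passed at 95 (highest other 0), and 134 differed among the 4 genotypes (highest other 12). In each comparison 1 of 100 splits, the real grouping, gave as many. The arrays of a genotype share 1 vehicle pool, so a difference between pools would also set the real grouping apart. These counts therefore do not separate receptor loss from pool differences. Splits that mix genotypes also remove differences other than the interaction, so they do not test the interaction by itself.

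Among the genes picked by the naming rule, some were called in opposite directions in 2 genotypes. From wild type to PXR deficiency these were Ppp1r3c (difference 0.67), Cyp27a1 (0.35), Cyp46a1 (-0.37), Nr2c1 (-0.51) and Nr5a1 (-0.53), and from wild type to CAR/PXR deficiency Cyp3a11 (-3.28), Cyp4b1 (-0.61), Fgb (2.28), Crp (0.89) and Cyp2a12 (-0.51). Of the first 5, the last 3 did not fall past the threshold in PXR deficiency without array 2 of that genotype (-0.09, -0.09 and -0.10), and the wild-type calls ended for Ppp1r3c without wild-type array 2 (-0.22) and for the other 4 without wild-type array 1 (-0.13, 0.16, 0.24 and 0.22). From PXR to CAR/PXR deficiency they were Fgb (2.48), Slco1b2 (-1.65), Cyp2a12 (-0.74), Cyp2f2 (-0.74), Ppp1r3c (-0.73) and Abcc2 (-0.72), and from CAR to CAR/PXR deficiency Cyp3a11 (-2.60) and Fgb (2.01). Turning the CAR/PXR-deficient ratios would make the listed calls that involve this genotype agree by construction, because they were listed as opposite. Over all probes called in both wild type and CAR/PXR deficiency, 1 rose and 10 fell in both, and with the ratios turned these would be opposite. Other genes were called in opposite directions too, among them Cyp2j5 from wild type to PXR deficiency (0.61) and Cyp2d22 from PXR to CAR/PXR deficiency (-0.54), both chosen after their values were seen. In the authors' value table, the 31 control probes of the CAR-deficient columns correlated with the scanner values at -0.35 to -0.26, against 0.91 to 1 in the other genotypes, while their other 289 probes correlated at 0.41 to 0.96. The cause was not tested. Control probes entered no response, difference or list result, and their scanner ratios were used only in the check for exchanged channels below.

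Fgb and 6 unnamed probes rose at least 2-fold on the CAR/PXR-deficient arrays. Over these probes the vehicle pool lay lower than the other 3 pools (median -1.45 on the log2 scale) and the PCN-treated samples lay higher than in the other 3 genotypes (1.41). The probes were picked by their ratio on these arrays, so a lower pool, higher PCN samples or both largely follow from that choice. The values show only how the difference was split between normalised channel levels, and they do not test a cause. Control probe ratios correlated with those of wild type at 0.98, which argues against exchanged channels in the files. An exchange of RNA before labelling was not tested, and an effect of losing both receptors stays open.

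The differences between genotypes in response may come in part from the vehicle pools. For PXR deficient minus wild type, the pools differed by more than the PCN-treated samples at 86 of 117 probes (73.5%). The same held at 68.1% for CAR/PXR deficient minus wild type, 69.5% for CAR/PXR minus PXR deficient and 59.2% for CAR/PXR minus CAR deficient (54.1%, 51.9% and 55.2% with the CAR/PXR-deficient channels turned), and at 0 of 3 probes for CAR deficient minus wild type. An effect of receptor loss on basal expression would give the same pattern, and with 1 pool per genotype the 2 cannot be told apart. The side with the larger difference also depends on any shift of both channels between the arrays of 2 genotypes, which was not separated.

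A dye effect that is the same on all arrays could give wild-type responses without an effect of PCN. Of the 79 probes called in wild type, 65 (82.3%) differed among genotypes. Such an effect alone therefore does not explain the ratios of all genotypes at those probes. The difference may lie in another genotype or its vehicle pool, so the test cannot separate a dye effect from a wild-type response to PCN. A dye effect was not excluded for any of the 79 probes by this test.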

How the results depend on the processing

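The tests with position, probable slides, spots not found left out and the CAR/PXR-deficient ratios turned were chosen only after the result was seen; the other settings were fixed before the data were examined. Counts are probes passing, and the cause of a change was not tested unless it follows from the construction. With median centring 38 passed in wild type, 44 in PXR deficiency, 0 for CAR deficient minus wild type, 62 for PXR deficient minus wild type, 31 for CAR/PXR deficient minus wild type, 43 for CAR/PXR minus PXR deficient, 29 for CAR/PXR minus CAR deficient, 28 for the interaction and 61 among the 4 genotypes. With the authors' values 45 passed in wild type, 0 for CAR deficient minus wild type, 58 for the interaction and 82 among the 4 genotypes. At a change of at least 1.5-fold, which by construction lowers counts, 10 passed in wild type, 10 in CAR, 10 in PXR and 11 in CAR/PXR deficiency, and in the same order of differences 1, 18, 19, 27, 14 and, for the interaction, 36. With 3 arrays per genotype, which by construction lowers power, the low position gave 45 in wild type, 27 in PXR and 36 in CAR/PXR deficiency, differences of 0, 43, 28, 37 and 27, an interaction of 25 and 55 among the 4 genotypes. The high position gave 12, 8, 31 and 22 for the responses, 0, 20, 24, 37 and 24 for the differences, 25 for the interaction and 35 among the 4 genotypes. With the genotype's arrays alone 23 passed in CAR and 54 in PXR deficiency. CAR deficient minus wild type gave 0 with scale normalization and 1 each with array weights, medians over spots, probable slides (correlation 0.13) and the 12 arrays alone. Without single arrays, wild type gave 47 (wild-type array 1 or 2) to 102 (PXR-deficient array 2), CAR/PXR deficiency 38 (array 6) to 67 (PXR-deficient array 2), and CAR deficient minus wild type 1 (wild-type 1 or 2, CAR-deficient 1 or 3), 6 (wild-type 3) and 5 (PXR-deficient 2). In the PXR-deficient pool 1 probe differed 2-fold with median centring. Centring on the luciferase reference was not run, because its probes are not named here, and a fit with slide or scan date was not run, because these were not given in the sources used here.

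With replicate number as a block, counts were 77, 35, 82 and 54 for the responses, 4, 113, 42, 92 and 48 for the differences, 91 for the interaction and 131 among the 4 genotypes. Of 36 same-number pairs, 9 correlated over 0.1, so the numbers do not pair arrays. This block ended the calls of Mvd and Ebp in wild type, Fgb and ST_Mm_222 in CAR deficiency, ST_Mm_281 in PXR deficiency and Cyp8b1 in CAR/PXR deficiency. For lists, fry called 2 in wild type, 3 in CAR, 4 in PXR and 2 in CAR/PXR deficiency, 4 for PXR deficient minus wild type and 3 for CAR/PXR deficient minus wild type, and an estimated correlation gave 0 in CAR deficiency, 0 in PXR deficiency and 0 for CAR/PXR deficient minus wild type. Median centring called 1 list in wild type, and no background correction and the authors' values 1 each in CAR/PXR deficiency.

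In 62 results the sign turned, of which 0 passed before or after. With median centring Cyp7a1 (-0.02), Cyp8b1 (0.05), Per2 (-0.02), Ch25h (-0.04) and Cyp21a1 (-0.03) turned in wild type and Nr1i3 in CAR (-0.02) and CAR/PXR deficiency (-0.05). With the authors' values Cyp8b1 (0.07), Foxo1 (0.01) and Cyp17a1 (0.06) turned in wild type and Nr1i3 in CAR/PXR deficiency (-0.03). Without background correction Pklr (0.01) and Foxo1 (0.03) turned in wild type, Nr1i3 in CAR/PXR deficiency (-0.02) and Nr1i2 in the PCN channel of CAR deficiency (-0.01). With print-tip loess Nr1i3 in CAR/PXR deficiency (-0.01) and Foxo1 in wild type (0.01) turned. Foxo1 was 0.02 with background subtraction, 0.02 with scale normalization, 0.04 with array weights, 0 with medians over spots and 0.02 with spots not found left out, and Cyp24a1 was 0.01 with array weights and 0.03 with medians over spots. With single arrays left out Pklr ranged from -0.05 to 0, Foxo1 from -0.03 to 0.04 and Cyp24a1 from -0.05 to 0.01. Lists turned with fry in wild type for bile acid, cholesterol and clock genes (adjusted p = 0.772 each), in PXR deficiency for bile acid (0.515) and SREBP genes (0.808), for transporters in CAR deficient minus wild type (0.477), for bile acid (0.382), clock (0.213) and transporter genes (0.144) in PXR deficient minus wild type and for nuclear receptors in CAR/PXR deficient minus wild type (0.937). With median centring the adjusted p was 0.986 for cholesterol genes in wild type, 0.656 for nuclear receptors in CAR deficiency, 0.959 for bile acid and SREBP genes in PXR deficiency, 0.814 for clock and steroid genes in CAR/PXR deficiency, 0.791 for drug oxidation in CAR deficient minus wild type, 0.983 for bile acid and 0.96 for clock and transporter genes in PXR deficient minus wild type and 0.851 for clock genes in CAR/PXR deficient minus wild type. Without background correction it was 0.89 for nuclear receptors in CAR deficiency, 0.969 for bile acid genes in PXR deficiency and 0.876 for clock genes in PXR deficient minus wild type. With the authors' values it was 0.94 for bile acid and 0.77 for clock genes in wild type, 0.733 for clock and 0.882 for glucose genes in CAR deficiency, 0.88 for bile acid genes in PXR deficiency, 0.897 for drug oxidation in CAR deficient minus wild type, 0.904 for bile acid, clock and drug oxidation genes in PXR deficient minus wild type and 0.989 for clock genes in CAR/PXR deficient minus wild type.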

Other observations

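The relation between risen and fallen probes was fixed before its value was seen, and no tests here were chosen only after the result was seen. The genes in the next paragraph were picked after their values were seen.

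Acss2, an acetate-activating enzyme of lipid synthesis, was at 0.23 in wild type and -0.25 in PXR deficiency, where it passed, and differed between these by -0.48. Fos, an immediate early transcription factor, fell in CAR (-0.30), PXR (-0.20) and CAR/PXR deficiency (-0.22) and was at -0.11 in wild type. Ppia, used elsewhere as a reference gene, rose in wild type (0.16), CAR (0.24) and PXR deficiency (0.16). Mlxipl, a glucose-responsive transcription factor, rose in CAR deficiency (0.15), and Hnf4a passed in 0 of the 4 responses.

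A hypothesis was that samples of any genotype with higher ratios of the 7 risen probes of CAR/PXR deficiency have lower ratios of the 33 probes that fell there. Within genotypes, over the 18 arrays of the other 3 genotypes, the correlation of the medians was -0.03 (permutation p = 0.899, rank correlation -0.20 with permutation p = 0.453). Without the 2 farthest arrays, PXR-deficient 1 and 2, it was -0.22. The data leave this open.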
